A study of Rattus norvegicus with 12 samples.

How the data were processed

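RNA of liver was measured in 12 male Brown Norway rats, an inbred strain, on 12 Affymetrix rat expression arrays of 1 chip type, 1 array per rat. Per the labels, 4 rats received water and 8 received D-penicillamine at 150 mg/kg in 1 mL, by a single oral gavage, and were killed 6 h later. Total RNA was isolated from frozen liver with a column kit, its quality was looked at by capillary electrophoresis, and 10 µg per rat entered the array procedure, per the labels' protocols. Groups and rat numbers were taken from the labels. The labels name individual rats, so each array is a biological replicate.

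The deposited table holds 15923 probe sets for the 12 arrays as log2 values to 2 decimals. Per the submitters' processing notes, the values were made with RMA, which corrects the background of the probe signals, normalizes the arrays to each other by quantiles and summarises the probes of each probe set. The version of RMA and any filter are not given in the sources used here. The values were taken as deposited, without a further transformation. Array medians lay between 6.30 and 6.35, and arrays correlated with each other at 0.987 to 0.998 over all probe sets other than controls. RMA values carry no detection call, so probe sets with little signal stayed in the tests, and the number of arrays limits the precision. Quantile normalization also gives all arrays nearly the same distribution, so a shift of most transcripts in 1 direction could not be seen in these values. The deposited scan records were used only for the chip lot, the day and the order of scanning, which are not measurements per the file headers.

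The 57 array controls were left out of the tests, which left 15866 probe sets. Probe sets were named from the platform annotation given with the table, with symbols updated through gene identifiers to those of the GRCr8 rat assembly. Of the probe sets tested, 12783 had 1 gene symbol, 312 had several and 2771 had none in that annotation. Probe sets with several symbols were not named. The named ones cover 10411 genes. No genome build is stated with the values, so no coordinates are given.

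The comparison of D-penicillamine with vehicle was fitted in limma 3.58.1 under R 4.3.3, with lmFit on an intercept and a group term and eBayes at its default settings, two-sided. P-values were adjusted by the Benjamini-Hochberg method over all 15866 probe sets, with a threshold of 0.05. Differences are D-penicillamine minus vehicle on the log2 scale, so positive values are higher after the drug. Intervals are 95% intervals from the moderated fit. In simulated data with known changes, made from the spread of these arrays with 8 against 4 samples, the fit recovered 97.0% of changes of 0.5 on the log2 scale, 100% of changes of 1 and 100% of changes of 2, with 3.41% of calls false. These changes were placed in 67, 67 and 66 probe sets at once, with noise drawn independently for each probe set and array. The simulation held no correlation between genes and no shared differences between arrays. It therefore does not exclude changes of these sizes in the real data.

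Before the data were examined, 36 gene lists were fixed, 25 of pathways or processes and 11 of cell type markers, with 917 distinct gene names, of which 909 matched a current symbol. The 34 lists with at least 5 measured genes were tested. Each gene entered once, by the probe set with the highest mean over all arrays. The test was camera in limma with a preset correlation between genes of 0.01, adjusted over the 34 lists. Members were also adjusted over the list alone. Because genes of a pathway are correlated between rats, the same test with a correlation estimated per list is given beside each call. The test fry asks whether a list's genes move on balance in 1 direction, and its mixed p asks whether they change in either direction. Neither compares a list with other genes.

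The genes named in the text follow a rule also fixed beforehand. It takes up to 12 genes per direction past the threshold and, where fewer pass, fills up to 6 per direction by smallest p, as values that did not pass. It adds up to 4 members with the smallest p of each list past its threshold, and 19 fixed genes whatever their values. Fixed genes with no probe set of that single symbol are not reported. Genes outside the rule are said to have been chosen after their values were seen.

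The spread between rats was the root mean square distance of each array from its group's mean, scaled for group size. RNA quality was the mean log2 difference between the 3' and 5' control probe sets of Gapdh and beta-actin, which grows when transcripts are degraded or labelled incompletely. Both were compared between groups with a two-sided exact permutation test over the 495 splits of 12 arrays into 8 and 4, whose smallest possible p is 0.00202.

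The scan records give 1 chip lot and 1 scan day. All 4 vehicle arrays were scanned before the first D-penicillamine array, so the order of scanning and the group cannot be told apart.

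Alternatives fixed beforehand were median centring and a further quantile normalization, the 7933 brighter probe sets, the trend and robust options of eBayes, array weights, 1 probe set per gene, a minimum fold of 1.5, the mean of a gene's probe sets, the estimated correlation and fry, the 3' minus 5' difference as a covariate of single probe sets, a block on the rat numbers both groups share, and leaving out each rat in turn. Leaving out vehicle rat 3 and D-penicillamine rat 4 together, the mixed p of fry and the 3' minus 5' covariate for the lists were added after seeing the data.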

Results

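The data describe the liver transcriptome of 12 male Brown Norway rats of 150 to 170 g, 6 h after a single oral gavage. Vehicle rats received water (n = 4), and treated rats received D-penicillamine at 150 mg/kg (n = 8). D-penicillamine is a thiol amino acid that binds copper and is used against Wilson's disease and rheumatoid arthritis. The title of the series places the experiment among studies of idiosyncratic drug reactions, that is, reactions that occur in some individuals only. The comparison therefore asks which liver transcripts differed between treated and untreated rats at an early time, and whether treated rats differed more among themselves. Every array gave 15923 log2 values, of which 15866 were tested.

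At the level of single transcripts most estimated differences were small, and none passed the threshold in the reported fit. In the limma fit 0 of 15866 probe sets passed an adjusted p of 0.05, and the smallest adjusted p was 0.147. An unadjusted p under 0.05 was reached by 977 probe sets, 425 higher and 552 lower after D-penicillamine, where 793.3 are expected by chance. Groups that did not overlap at all were seen for 91 probe sets, 31 higher and 60 lower, where chance gives 64.1 (0.404% of probe sets). For 99.7% of probe sets the 95% interval of the difference lay within a 2-fold change in either direction, and for 98.6% within a 1.5-fold change. These shares cover all probe sets tested, those with little signal included. The median absolute difference was 0.048. With array weights 2 probe sets passed, those of Dbp (adjusted p = 0.0149) and Inhba (0.0439). Without D-penicillamine rat 1, only Dbp passed (adjusted p = 0.00384). In the other settings the smallest adjusted p lay between 0.0881 and 0.491.

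Dbp, a transcription factor driven by the circadian clock, lay 0.69 higher after D-penicillamine (SE 0.11, 1.61-fold, adjusted p = 0.160) and was above the vehicle mean in 8 of 8 treated rats. Inhba, which encodes a subunit of activin, lay at -0.34 (SE 0.05, adjusted p = 0.147) and was below the vehicle mean in 8 of 8. Acvr1, a receptor for bone morphogenetic proteins and activin, differed by 0.29 (SE 0.06). Por, the reductase that passes electrons to microsomal cytochromes P450, differed by 0.67 (SE 0.13), and its other probe set by 0.55 (SE 0.13). Nr1d1, a repressor of the clock, differed by 0.77 (SE 0.17), Zfp574 by 0.35 (SE 0.08), and Il6r, the receptor of interleukin-6, by 0.58 (SE 0.13). On the lower side stood Hmgn3 at -0.24 (SE 0.05), Rbm39 at -0.43 (SE 0.09), G3bp2 at -0.23 (SE 0.05), Herc3 at -0.29 (SE 0.06) and Rprm at -0.41 (SE 0.09). Other probe sets of the same genes differed less for Rbm39 (-0.14, -0.11 and -0.096) and Zfp574 (0.115 and 0.039), and that of G3bp2 had the opposite sign at 0.064 (SE 0.08). By the probe sets given first, each of these 12 genes deviated in the same direction from the vehicle mean in 8 of 8 treated rats, and none passed the adjustment over all probe sets in the reported fit. Genes chosen by their p on the same arrays tend to show such agreement.

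Genes of the circadian clock changed, in both directions, and had the smallest mixed p in fry among the 34 gene lists. Of 17 measured members, 8 passed when adjusted over the list alone and 0 over all probe sets, 6 of them higher and 2 lower after D-penicillamine. Higher were the nuclear receptors Nr1d1 (1.71-fold) and Nr1d2, which repress Bmal1, at 0.54 (SE 0.14), the output factors Dbp and Tef, the latter at 0.15 (SE 0.05), Bhlhe40 at 0.70 (SE 0.23) and the deubiquitinase Usp2 at 0.34 (SE 0.13). Lower were Bmal1, the activator of the clock, at -0.32 (SE 0.10), and Nfil3, a repressor that acts against Dbp, at -0.57 (SE 0.13). All 8 deviated in the same direction from the vehicle mean in 8 of 8 treated rats, which their choice by p on the same arrays favours. Tef, Bhlhe40, Usp2, Bmal1, Per2 and Clock are given after their values were seen. Members that did not pass included Per1 at 0.04 (SE 0.06), Per2 at -0.07 (SE 0.17) and Clock at -0.03 (SE 0.09). The mixed p of fry, which tests change in either direction and was added after seeing the data, gave an adjusted p of 2.0e-05. In camera the list sat higher with a median of 0.083 (adjusted p = 0.0030), and adjusted p = 0.339 with an estimated correlation. The call of camera was also lost on the 7933 brighter probe sets (adjusted p = 0.150) and with the 3' minus 5' difference as a covariate (0.0783), and over the 20 alternative settings of camera its adjusted p ran from 6.9e-04 to 0.339. All vehicle arrays were scanned before all D-penicillamine arrays, and the clock hours at which the rats were dosed and killed are not given in the sources used here.

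**Figure D1:**
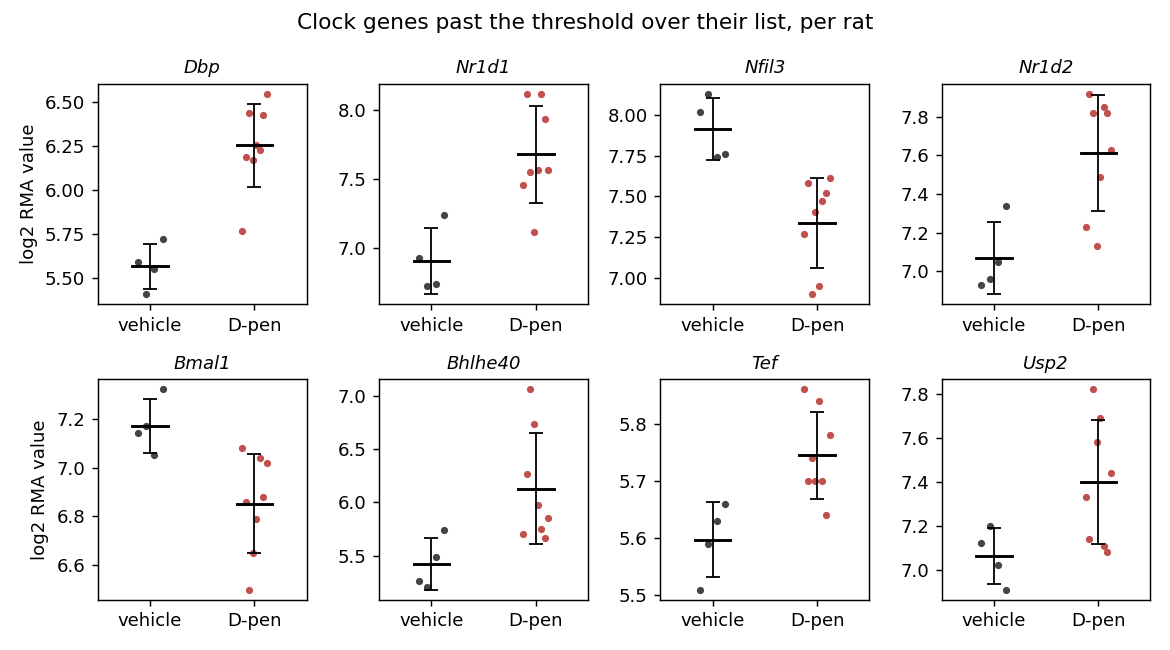
Log2 RMA values of the 8 clock genes that passed over their own list (y axis) in the vehicle rats (n = 4) and in the D-penicillamine rats (n = 8, labelled D-pen), with 1 point per rat, a bar at the group mean and whiskers of 1 SD. Dbp was at 5.57 in vehicle and 6.25 in D-penicillamine rats, and Nfil3 at 7.91 and 7.34.

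In all, 9 of the 34 lists passed camera at the preset correlation and 0 passed with the correlation estimated per list. The directional p of fry passed 0 lists, and the mixed p passed 2, the clock list and the immediate early genes. Without D-penicillamine rat 6 the count in camera was 4, and without rat 1 or rat 8 it was 5. Without vehicle rat 3 and D-penicillamine rat 4 together it was 8.

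**Figure D2:**
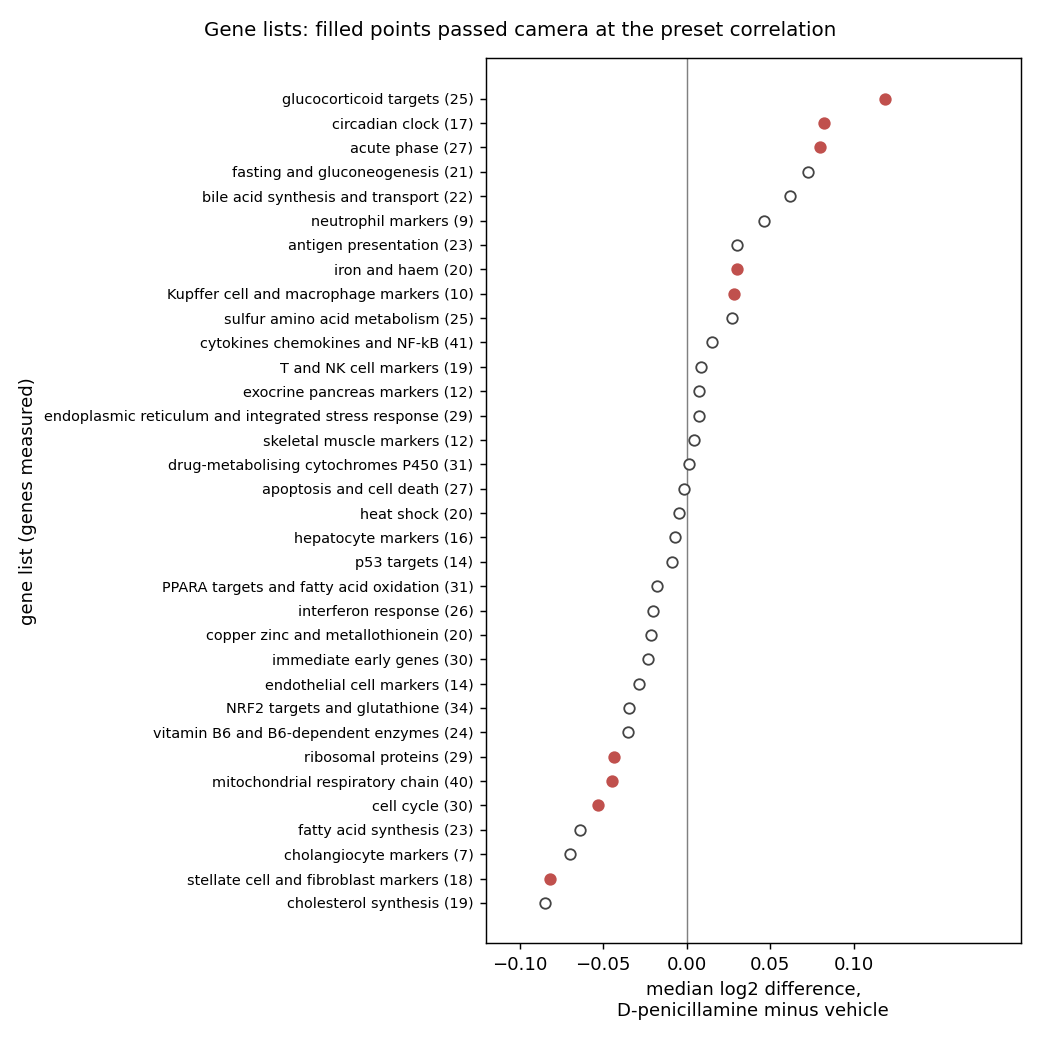
Median log2 difference, D-penicillamine minus vehicle, over the measured genes of each of the 34 tested lists (x axis), with the number of genes measured in brackets (y axis); filled points passed camera at the preset correlation and open points did not. Medians ran from -0.085 for cholesterol synthesis to 0.119 for glucocorticoid targets.

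The list of acute phase genes, which the liver transcribes in response to inflammatory cytokines, sat higher on balance after D-penicillamine, but several of its main plasma proteins hardly differed. Of 27 measured members 25 had a positive difference, with a median of 0.080 and a mean of 0.167 (adjusted p = 2.5e-05 in camera, and adjusted p = 0.511 with an estimated correlation). Il6r was the 1 member that passed over the list alone (adjusted p = 0.0129). Values that did not pass included the iron-regulating hormone Hamp at 0.58 (SE 0.25), Orm1, an acid glycoprotein of plasma, at 0.29 (SE 0.13), and the interleukin-1 receptor Il1r1 at 0.12 (SE 0.06). Single vehicle rats carried much of these values, since Hamp was at 0.25 without vehicle rat 1, Orm1 at 0.19 without vehicle rat 2 and Il1r1 at 0.054 without vehicle rat 3. The other probe set of Il1r1 was at 0.31 (SE 0.08). Among the fixed genes, Crp differed by 0.11 (SE 0.09) and A2m by 0.04 (SE 0.19), and the cytokine gene Il1b by -0.0013 (SE 0.09). The following members are given after their values were seen. Lcn2 had the largest absolute difference of all probe sets at 1.01 (SE 0.50) and did not pass over the list alone. Hp was at 0.028 (SE 0.04), Fga at 0.021 (SE 0.07), Fgb at -0.019 (SE 0.07), Fgg at 0.035 (SE 0.05) and C3 at -0.014 (SE 0.04). The directional p of fry, which tests the same shift without comparing it with other genes, did not pass (adjusted p = 0.750). The call in camera held without any single rat, D-penicillamine rat 4 included.

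The iron and haem list, which shares Hamp, Hp and Hpx with the acute phase list, passed in the higher direction (median 0.030, adjusted p = 0.0426, and adjusted p = 0.339 with an estimated correlation). Smad7, which restrains bone morphogenetic protein signalling in the liver, was its 1 member past the list-wide threshold at 0.26 (SE 0.07), with 0.18 and 0.03 on its other probe sets. Id1, a target of the same signalling, differed by 0.29 (SE 0.11), and the iron exporter Slc40a1 by 0.14 (SE 0.08), which fell to 0.028 without vehicle rat 3 and was 0.034 and 0.015 on its other probe sets. The call was lost on leaving out any of vehicle rats 1, 2 and 4 or D-penicillamine rats 2, 3, 5, 6, 7 and 8, with adjusted p between 0.0538 and 0.132. It was also lost on median centring (adjusted p = 0.0547), a further quantile normalization (0.0564), the brighter probe sets (0.112) and the mean of a gene's probe sets (0.102). The replicate block over rat numbers 1 to 4, which leaves out D-penicillamine rats 5 to 8, lost the call too (median 0.026, adjusted p = 0.130). In all it was lost in 17 of 22 settings. Markers of Kupffer cells, the macrophages of the liver, also passed (10 measured, 9 positive, median 0.028, adjusted p = 0.0366, and adjusted p = 0.950 with an estimated correlation). None of the 10 passed over the list alone. The complement genes C1qc and C1qb differed by 0.16 (SE 0.07) and 0.13 (SE 0.08), Tyrobp by 0.12 (SE 0.05) and Csf1r by 0.12 (SE 0.05). Without vehicle rat 2, C1qc was at 0.107 and C1qb at 0.062. This call was lost without vehicle rat 2, 3 or 4 or D-penicillamine rat 1, 6 or 8, with medians between 0.016 and 0.055 and adjusted p between 0.0571 and 0.155. It was lost in 14 of 22 settings in all, among them the 3' minus 5' covariate (adjusted p = 0.275), a further quantile normalization (0.0537), the brighter probe sets (0.0511), the mean of a gene's probe sets (0.0738) and the data without vehicle rat 3 and D-penicillamine rat 4 together (0.204). In that order the medians were 0.046, 0.043, 0.028, 0.028 and 0.058, so the median did not fall in these settings.

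Glucocorticoid targets passed in the higher direction with 19 of 25 members positive (median 0.119, adjusted p = 0.0366, and adjusted p = 0.856 with an estimated correlation). Its members past the list-wide threshold went opposite ways. Klf15, a factor of amino acid catabolism, was higher by 0.36 (SE 0.10), and Mt1, a metal-binding metallothionein, was at -0.64 (SE 0.17). Klf9 differed by 0.61 (SE 0.23) and Fkbp5 by 0.20 (SE 0.09), neither past the list-wide threshold. Without vehicle rat 1, Klf15 was at 0.23 and Klf9 at 0.36, and the other probe sets of Klf9 were at 0.46 and 0.058. Among the fixed targets Tat differed by 0.23 (SE 0.29), Pck1 by -0.16 (SE 0.10), Igfbp1 by -0.35 (SE 0.50) and Cdkn1a by 0.16 (SE 0.10), these with intervals that include 0. Mt2A, a further fixed target, was at -0.58 (SE 0.27), against the direction of the list. Its interval of -1.15 to -0.012 excluded 0, and it did not pass the list-wide threshold. Pck1 reached -0.26 without vehicle rat 1, and Cdkn1a reached 0.25 without vehicle rat 3. The list's call was lost without vehicle rat 1 or D-penicillamine rat 1, 3, 5, 6 or 8, with medians between 0.048 and 0.1125 and adjusted p between 0.0543 and 0.523. It was also lost after a further quantile normalization (median 0.131, adjusted p = 0.0564) and on the brighter probe sets (median 0.138, adjusted p = 0.101).

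On the lower side were the lists of the mitochondrial respiratory chain, ribosomal proteins, cell cycle and stellate cell markers. Of 40 respiratory chain genes 32 were negative, 5 positive and 3 at 0 (median -0.044, adjusted p = 0.0118, and adjusted p = 0.973 with an estimated correlation), with Ndufb5 at -0.21 (SE 0.08), Cox6c at -0.09 (SE 0.04), Ndufs6 at -0.10 (SE 0.06) and Atp5mc3 at -0.093 (SE 0.05). Of 29 ribosomal protein genes 23 were negative (median -0.044, adjusted p = 0.0366, and adjusted p = 0.973 with an estimated correlation), with Rps9 at -0.10 (SE 0.05), Rpl5 at -0.095 (SE 0.05), Rps3 at -0.10 (SE 0.06) and Rpl14 at -0.11 (SE 0.06). No member of either list passed over its list alone. Vehicle rat 3, whose 3' minus 5' control difference was 1.185 against 0.43 to 0.605 in the 11 other rats, had the highest mean of both lists. Without it Ndufb5 was at -0.10, Cox6c at -0.056 and Ndufs6 at -0.054, the medians were -0.0025 and -0.0058 and neither list passed (adjusted p = 0.976 and 0.972). Without D-penicillamine rat 1 neither passed either, and the ribosomal list was also lost without D-penicillamine rat 8. Both were lost with the 3' minus 5' covariate (adjusted p = 0.912 and 0.633), without vehicle rat 3 and D-penicillamine rat 4 together (0.640 for both) and after a further quantile normalization (0.0564 and 0.117), and the ribosomal list on the brighter probe sets (0.0511).

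Of 30 cell cycle genes 23 were negative (median -0.053, adjusted p = 0.0118, and adjusted p = 0.950 with an estimated correlation). Ccnb1, a cyclin of mitosis, was at -0.18 (SE 0.06), the microtubule regulator Stmn1 at -0.28 (SE 0.10) and the kinase gene Cdk4 at -0.11 (SE 0.04), while Cks2 was at 0.19 (SE 0.07). Of 18 markers of stellate cells and fibroblasts 12 were negative (median -0.082, adjusted p = 0.0366, and adjusted p = 0.950 with an estimated correlation). The matrix genes Lum and Lox were at -0.20 (SE 0.06) and -0.68 (SE 0.28), the smooth muscle actin gene Acta2 at -0.18 (SE 0.08) and Pdgfrb at -0.13 (SE 0.06), or -0.064 without vehicle rat 1. No member of these lists passed over its list alone. The cell cycle call was lost without vehicle rat 2 or D-penicillamine rat 6 (adjusted p between 0.0571 and 0.0920) and on the brighter probe sets (0.233). It was also lost with the replicate block, which leaves out D-penicillamine rats 5 to 8 (median -0.0425, adjusted p = 0.258). The stellate call was lost without vehicle rat 1 or 4 or D-penicillamine rat 3, 5, 6, 7 or 8 (between 0.0571 and 0.576), on the brighter probe sets (0.150) and after a further quantile normalization (0.0564). With the same block, again without D-penicillamine rats 5 to 8, it was lost as well (median -0.056, adjusted p = 0.773).

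**Figure D3:**
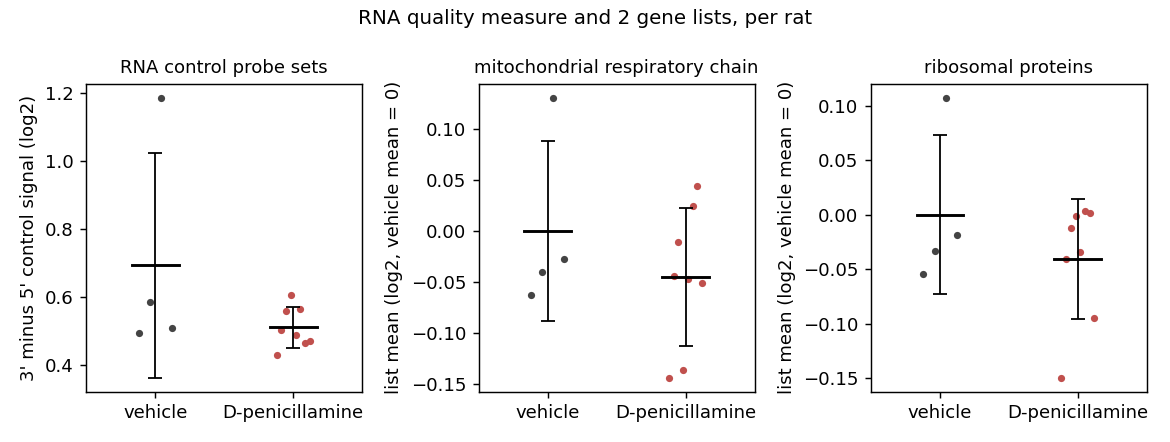
The log2 difference between 3' and 5' control probe sets (y axis, left) and the mean of the respiratory chain and ribosomal protein lists relative to the vehicle mean (log2, y axis, middle and right), per rat in the vehicle (n = 4) and D-penicillamine (n = 8) groups, with the group mean and whiskers of 1 SD. Vehicle rat 3, at 1.185 on the left, is also the highest vehicle point in the middle (0.131) and on the right (0.107).

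The lists that bear on the chemistry of the drug gave no set call with all 12 rats. The copper, zinc and metallothionein list had a median of -0.021 over 20 genes (adjusted p = 0.838). It held 2 members past the list-wide threshold, Mt1 and the zinc exporter Slc30a1, the latter at 0.58 (SE 0.15) and named after its value was seen. Mt2A was at -0.58 (SE 0.27) with an SD of 0.62 in treated rats against 0.092 in vehicle rats. The NRF2 and glutathione list, which responds to thiol stress, had a median of -0.034 over 34 genes (adjusted p = 0.756), with Hmox1 at 0.03 (SE 0.05), Gclc at -0.20 (SE 0.14) and Nqo1 at 0.16 (SE 0.17). On leaving out each rat Hmox1 ran from 8.3e-04 to 0.081, Gclc from -0.30 to -0.12 and Nqo1 from 0.027 to 0.20. The other probe set of Gclc was at -0.0575 (SE 0.18). Vitamin B6 enzymes had a median of -0.035 over 24 genes (adjusted p = 0.337) and sulfur amino acid metabolism 0.028 over 25 genes (adjusted p = 0.561). The former passed camera without vehicle rat 1 (median -0.076, adjusted p = 0.0461), and the latter without vehicle rat 3 and D-penicillamine rat 4 together (0.061, adjusted p = 0.0032). In the bile acid list (median 0.062, adjusted p = 0.115) the receptor Nr0b2 passed over the list alone at 0.99 (SE 0.26), named after its value was seen, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -0.11 (SE 0.26). That list passed camera without D-penicillamine rat 4 (0.093, adjusted p = 0.0019) and without it and vehicle rat 3 together (0.048, adjusted p = 0.0317). Of 31 genes of drug-metabolising cytochromes P450, Por and Cyp3a2 (0.31, SE 0.09) passed over the list alone, the latter named after its value was seen, and the list had a median of 0.0013 (adjusted p = 0.579), or 0.036 (adjusted p = 0.0466) without D-penicillamine rat 4.

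Immediate early genes, which respond to growth factors and stress, did not shift as a set (median -0.023, adjusted p = 0.252), but fry's mixed p passed (adjusted p = 0.0092), and 0 of the 30 members passed over the list alone. Fasting and gluconeogenesis genes had a median of 0.073 (adjusted p = 0.337), fatty acid synthesis -0.064 (0.0905), cholesterol synthesis -0.085 (0.115), PPARA targets and fatty acid oxidation -0.018 (0.838), heat shock -0.0044 (0.838) and the endoplasmic reticulum stress response 0.0075 (0.374). Cholesterol synthesis passed without vehicle rat 2 or 4 or D-penicillamine rat 3, 4 or 7 (adjusted p between 0.0123 and 0.0388). Fatty acid synthesis passed without D-penicillamine rat 3, 4 or 8 (between 0.0163 and 0.0486). It also passed with the block on rat numbers (0.0240), which leaves out the D-penicillamine rats whose numbers no vehicle rat shares. Hspa1a was at -0.15 (SE 0.07) and Atf3 at -0.02 (SE 0.06). Medians were -0.020 for interferon response (adjusted p = 0.561), 0.030 for antigen presentation (0.337), 0.015 for cytokines, chemokines and NF-kB (0.598), -0.0088 for p53 targets (0.941) and -0.0013 for apoptosis (0.640). In the fatty acid synthesis list Fads1 passed over the list alone at -0.39 (SE 0.10), and in the p53 list Mdm2 did at 0.32 (SE 0.08), both named after their values were seen.

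Among the other cell types, markers of hepatocytes had a median of -0.0069 (adjusted p = 0.981), neutrophils 0.046 (0.193), T and NK cells 0.0087 (0.941), endothelial cells -0.029 (0.950), cholangiocytes -0.070 (0.990), exocrine pancreas 0.0075 (0.884) and skeletal muscle 0.0044 (0.902). For heat shock, apoptosis, hepatocytes, cholangiocytes, exocrine pancreas and skeletal muscle, the median, the mean and the direction of the test did not all have the same sign. Markers of B cells and of erythroid cells, with 2 and 4 genes measured, were too few to test, and their medians were -0.013 and 0.048.

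Treated rats did not differ detectably more among themselves than vehicle rats. The root mean square distance to the group mean was 0.132 ± 0.029 (SD, n = 8) after D-penicillamine and 0.121 ± 0.029 (SD, n = 4) after water, and the difference of 0.011 gave an exact permutation p of 0.582. D-penicillamine rat 4 lay farthest from its group at 0.195, and without it the difference was -3.5e-04. Leaving out the other rats in turn gave differences from -0.0034 without vehicle rat 4 to 0.033 without vehicle rat 3. Vehicle rat 3, whose 3' minus 5' control difference was the highest, lay farthest from the vehicle mean at 0.162. Without it the exact permutation p was 0.0848. Without it and D-penicillamine rat 4 together the difference was 0.021 (exact permutation p = 0.0917). The 3' minus 5' control difference was 0.511 ± 0.060 (SD, n = 8) in treated and 0.694 ± 0.330 (SD, n = 4) in vehicle rats, a difference of -0.18 with an exact permutation p of 0.103. Without vehicle rat 3 that difference was -0.019.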

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

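The tests of the respiratory chain and ribosomal lists apart from the cell cycle and stellate lists were chosen after the results were seen. A rat is given here when it stood so far from the rest of its group that chance would place it there in about 1 of 20 groups. Of 190 groups looked at, 16 held such a rat, where 9.5 are expected by chance.

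D-penicillamine rat 4 accounted for 6 of the 16 values. Its mean was lowest for hepatocyte markers (-0.12, others 0.018 to 0.060), vitamin B6 enzymes (-0.33, others -0.085 to 0.077), sulfur amino acid metabolism (-0.24, others -0.019 to 0.079) and PPARA targets (-0.27, others -0.061 to 0.071). Its Hamp value was 11.43 against 12.07 to 12.41 in the other treated rats, and its Nqo1 value 8.41 against 7.19 to 7.62.

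Vehicle rat 3 accounted for 4 values. Its 3' minus 5' control difference was 1.185 against 0.495 to 0.585 in the other vehicle rats. Its Slc40a1 value was 9.02 against 9.46 to 9.49, its Cdkn1a value 7.88 against 7.45 to 7.52, and its mean for sulfur amino acid metabolism 0.096 against -0.036 to -0.025.

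The remaining rats given here stood apart in 1 or 2 measures each. Herc3 was 6.40 in vehicle rat 4 against 6.33 to 6.34, and Pck1 was 12.28 in vehicle rat 1 against 12.66 to 12.73. The vitamin B6 mean of vehicle rat 1 was -0.12 against 0.037 to 0.043. Stmn1 was 6.47 in D-penicillamine rat 6 against 6.88 to 7.08, and Igfbp1 was 6.11 in D-penicillamine rat 3 against 8.47 to 9.63. The antigen presentation mean of D-penicillamine rat 1 was 0.16 against -0.043 to 0.041.

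The lower respiratory chain, ribosomal, cell cycle and stellate lists were set against vehicle rat 3, whose 3' minus 5' control difference was the highest. That difference cannot tell degraded RNA from incomplete labelling. For the 4 lists as a set, the mean of the medians went from -0.056 to -0.029 without that rat and 2 of the 4 lists still passed, which leaves the question open for the set. For the respiratory chain and ribosomal lists the mean median went from -0.044 to -0.0042 and neither passed, so their call depended on that sample. It did not depend on that sample alone, since neither list passed without D-penicillamine rat 1 either. Even with all rats, the joint mean of these lists did not differ detectably between groups (-0.043, exact permutation p = 0.317). For the cell cycle and stellate lists the mean median went from -0.068 to -0.053 without vehicle rat 3, which argues against that rat as the whole cause. Both lists passed, and their joint mean still differed between groups (-0.082, exact permutation p = 0.0121). The lists were picked because they sat lower in these same rats, so that p adds no separate evidence. Passing camera at the preset correlation adds little. With an estimated correlation neither list passed camera with all rats (adjusted p = 0.950 for both). Both of the latter lists were lost with a replicate block over rat numbers 1 to 4 (medians -0.0425 and -0.056, adjusted p = 0.258 and 0.773). That setting also leaves out the D-penicillamine rats with higher numbers, so the loss cannot be put down to the block alone. A drug effect and the order of scanning remain open for both lists.

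The higher acute phase list was set against 3 explanations. Without D-penicillamine rat 4, whose acute phase mean was the highest at 0.366, the mean difference was 0.14 (SE 0.05) against 0.167 with all rats, and without vehicle rat 3 it was 0.19 (SE 0.07), and the list passed camera both times (adjusted p = 9.8e-04 and 4.5e-06). Both mean differences argue against either of these rats as the sole cause. The one without D-penicillamine rat 4 lay little more than 1 SE above the bound set beforehand. Passing camera at the preset correlation adds little, since with an estimated correlation the list did not pass with all rats (adjusted p = 0.511). With the macrophage marker score as a covariate it was 0.15 (SE 0.07) and the list passed camera (adjusted p = 1.05e-04), and the score differed by 0.059 (exact permutation p = 0.135), but 0.15 lies within 1 SE of the bound set beforehand, so a larger macrophage share stays open. A response to the drug and the order of scanning stay open and untested.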

How the results depend on the processing

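The alternatives without vehicle rat 3 and D-penicillamine rat 4 together, the mixed p of fry and the 3' minus 5' covariate for the gene lists were chosen after seeing the data. The count of 0 probe sets past the threshold in limma became 2 with array weights and ran from 0 to 1 on leaving out each rat (1 without D-penicillamine rat 1). In the other settings it was 0, with the smallest adjusted p between 0.0881 and 0.491. The 977 probe sets at an unadjusted p under 0.05 became 510 on the 7933 brighter probe sets and 646 with 1 probe set per gene, where fewer were tested, and 21 with a minimum fold of 1.5, a stricter condition. On leaving out each rat they ran from 712 to 1094. The 9 gene lists in camera became 3 after a further quantile normalization, 2 on the brighter probe sets, 5 with the 3' minus 5' covariate, 0 with the estimated correlation, 0 in directional fry and 2 in its mixed p. On leaving out each rat they ran from 4 (without D-penicillamine rat 6) to 13 (without rat 4), with 5 without rat 1 or rat 8. The cause was not tested. The acute phase list passed in each camera setting run at the preset correlation. The difference in spread ran from -0.0034 (without vehicle rat 4) to 0.033 (without vehicle rat 3), and the RNA quality difference was negative in each setting run.

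Directions reversed for 2 lists that had passed. With the covariate the medians of the respiratory chain and ribosomal lists were 2.4e-05 and 0.0039, and without both rats in doubt that of the respiratory chain was 0.0098. Of the 25 lists under the threshold, 22 changed the sign of their median in some setting. Of 59 named probe sets, 52 kept their sign in every setting run. The others were A2m, Atf3, Crp, Cyp7a1, Igfbp1, Il1b and Tat. Cyp7a1 was at 0.0061 with array weights, Crp at -0.014 with the covariate, Il1b at 0 with median centring, and without both rats in doubt Tat was at -0.043 and Crp at -0.046. On leaving out each rat, A2m ran from -0.091 to 0.17, Atf3 from -0.056 to 0.0175, Crp from -0.0225 to 0.1875, Cyp7a1 from -0.2725 to 0.12, Igfbp1 from -0.597 to 0.012, Il1b from -0.038 to 0.061 and Tat from -0.0375 to 0.49. The cause was not tested.

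The values gave no sign that the numbers shared by vehicle and treated rats pair them, though so few rats cannot exclude a pairing. Deviations of same-numbered rats correlated at 0.25, -0.16, 0.14 and -0.13, and none of the 4 vehicle rats correlated best with its own number. With a replicate block over numbers 1 to 4, 0 probe sets passed in limma, 934 had an unadjusted p under 0.05, 7 lists passed and A2m was at -0.0975. That setting also leaves out the D-penicillamine rats with higher numbers, so these values cannot be put down to the block alone. A block on scan batch was not run, because all arrays share 1 lot and 1 day. The values carry no detection call, so limits by signal over background were examined through the brighter probe sets alone.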

Other observations

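The clock index, its tests against vehicle rat 3 and against glucocorticoid targets, the mixed p of fry, and the counts of splits for probe sets past the threshold, for a fold of at least 1.5 and for the smallest mixed p over the lists were chosen after the results were seen.

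The differences of at least 1.5-fold at an unadjusted p under 0.05 came from 21 probe sets, and none passed the adjustment (named here after their values were seen). Beside Nr0b2 and the other genes given above, Hsd17b2, which inactivates sex steroids, was at 0.95 (SE 0.27) with all 8 treated rats outside the vehicle range, though 1 of them below it. Id2, an inhibitor of transcription factors, was at 0.84 (SE 0.22) and 0.67 (SE 0.22) on 2 probe sets. A further probe set of Usp2 was at 0.82 (SE 0.25), against 0.34 for the brighter one used in the clock list. On the lower side were both probe sets of Slc6a6, the taurine transporter, at -0.73 (SE 0.18) and -0.72 (SE 0.20) and below the vehicle mean in 8 of 8 rats. Also lower were Egr1, an immediate early transcription factor, at -0.84 (SE 0.26), Hhex at -0.76 (SE 0.35), Tsc22d1 at -0.73 (SE 0.23), each below the vehicle mean in 7 of 8 treated rats, and the linker histone gene H1f2 at -0.66 (SE 0.16) in 8 of 8. In 4 of 100 splits of the rats into 8 and 4, the real one included, as many probe sets met both limits, and the highest of the other splits gave 37 against 21. That is under 5 of 100, but the 100 were drawn from 495 splits and the count was chosen after the values were seen, so chance is left open for it.

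Other splits bear on the counts of the report as well. For the 0 probe sets past the threshold the splits decide nothing, since all 100 had to give at least 0, and the highest of the others gave 208. As many as 977 probe sets at an unadjusted p under 0.05 came from 22 of the 100, and the highest of the others gave 3646. As many as 9 gene lists came from 31 of the 100, with 14 as the highest of the others. Chance cannot be excluded for the counts of 977 and 9. The split with 3646 parted vehicle rat 1 and D-penicillamine rats 1, 4 and 5 from the rest, several times the real count, which points to a structure among the arrays that does not follow the drug. These 4 arrays have the lowest upper quartiles (7.52 to 7.58 against 7.59 to 7.63), a difference in the distribution of array values whose source was not tested. For the clock list, only the real split of the 100 gave a mixed p as small as 5.9e-07, and the smallest of the others was 5.4e-05, but this list was singled out as the smallest of 34. Over all 34 lists, 2 of the 100 splits, the real one included, gave a smallest mixed p of 5.9e-07 or less, and that of the other was 2.7e-07. That is under 5 of 100, but with 100 splits drawn from 495 and the mixed p chosen after the data were seen, chance is left open here too.

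The clock genes were examined with an index, the mean of 10 genes expected to rise in rodent liver during the day minus the mean of 3 expected to fall, which was -0.57 ± 0.20 (SD, n = 8) after D-penicillamine and -1.13 ± 0.06 (SD, n = 4) after water, a difference of 0.56 with an exact permutation p of 0.00202, the smallest that 495 splits can give. The index was built after clock genes were seen to differ between these same rats. Its p therefore restates that observation and adds no separate evidence. Without vehicle rat 3 the difference was 0.59 (SE 0.12), which argues against that rat, and so against degraded or incompletely labelled RNA in it, as the cause. A candidate explanation is that treated rats were killed later in the day, but over the 8 treated arrays the index did not rise detectably with the order of scanning (Spearman's rho = -0.048, exact permutation p = 0.935, Pearson's r = -0.21, exact permutation p = 0.620, both 0.935 after Benjamini-Hochberg adjustment, and r = -0.45 without the 2 arrays farthest from the middle). Because the hours are not given in the sources used here and the order of scanning need not follow them, sampling time and the drug cannot be told apart. A wider shift of glucocorticoid-responsive genes was also examined. The 24 such targets outside the clock list had a median of 0.12 (SE 0.06 over members). The clock genes past their list-wide threshold had a median absolute difference of 0.56. The median of the targets fell short of the bound set for this explanation but lay within 2 SE of it. Members measured in the same rats are also correlated, so the values do not decide it. A phase shift by the drug itself was not tested.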
